A study of Homo sapiens with 4 samples.

How the data were processed

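Total RNA from MDA-LM2 cells, a lung-metastatic line selected from the human breast cancer line MDA-MB-231, was measured on Illumina expression BeadChips 48 hours after transfection. Of the 4 arrays, 2 came from cells given a small interfering RNA (siRNA) against TARBP2, each with a different siRNA, and 2 from cells given a control siRNA. The 2 TARBP2 siRNAs were the 2 replicates of the knockdown group. The spread within that group therefore includes the difference between the siRNAs. Nothing in the labels says that the 2 control arrays came from separate cultures, so their spread may be technical. The p-values measure the spread between these samples.

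The deposited table of probe intensity values was not normalized, per the file headers, and its 4 columns had different quantiles. A detection score accompanied each intensity in the deposited table. The score rose with the signal of its own array and reached 1 for bright probes, so 1 minus the score was used as the detection p-value. In a separate deposited table of normalized intensity values, the 4 columns had the rank order of the raw signals of their arrays (Spearman correlation of 1 for each array) and shared their quantiles, with medians of 85.6 on each array. These values were therefore quantile-normalized on a linear scale by the authors, with no centring of genes. The submitters' processing notes name lumi, and its version and settings are not given in the sources used here. The authors' deposited table of comparisons holds 1 log fold change of TARBP2 siRNA over control siRNA for each of 39745 sequence accessions, with a class of 0 or 1, per the file headers. These deposited values were treated as log2 fold changes that the authors computed from the arrays. Of the 100 largest values, 40 lay within 0.001 of a probe's log2 difference between the mean knockdown and the mean control, and 48 did with the sign turned, so the values were not matched to this contrast beyond chance. The contrast behind the table, and the weight of each siRNA in it, stay unknown. The log base, the transformation, and the way probes and arrays were joined are not given in the sources used here. The 100 largest values averaged 0.875 of the 100 largest log2 ratios of the normalized probe values, whereas a natural logarithm would have given about 0.693, but the SD of all values was 0.758 of the SD of the mean log2 difference over all probes, so the base is not settled and log2 is an assumption. The class was 1 for values above 0.2 and 0 for all others: the lowest value with class 1 was 0.200012 and the highest with class 0 was 0.199963.

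Probes carry no gene names in the tables used here, and the values of the authors' deposited table could not be joined to single probes. The tests planned for genes were therefore run on probes, and named genes were described from the authors' deposited table, without an error or a number of replicates. The planned camera test of gene lists could not be run for the same reason. Accessions were matched without versions to the RefSeq gene table of GRCh38.p14, which gave a symbol to 22411 accessions (56.4%), to 91.5% of the curated accessions (prefix NM or NR) and to 19468 genes. The value of a gene was the mean over its accessions (records). Older symbols in the gene lists were brought up to date through the same table, and 6 list entries found no symbol.

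Probe intensities were background-corrected and quantile-normalized with neqc in limma 3.58.1 (R 4.3.3), with an offset of 16 and negative controls inferred from the detection p-values. Probes with a detection p under 0.05 on at least 2 arrays were kept, 21075 of 47321. Groups were compared with limma (lmFit and eBayes with an intensity trend, two-sided) and Benjamini-Hochberg adjustment at 0.05. With 2 arrays against 2, an exact permutation test of a single value cannot go under p = 0.333. Agreement between the siRNAs was described by the correlation across probes of differences from different control arrays, and with shared controls beside 100 simulations of unchanged arrays. Each siRNA was also set against the 2 controls with the spread of the control pair, a fit chosen after seeing the data that assumes a lone array to vary as the controls did. The test was run on simulated data for the 21075 probes, of which 200 were changed.

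The gene lists and the rule for named genes were fixed before the data were examined. The 26 lists cover the small RNA, m6A and mRNA decay machinery, the amyloid precursor pathway, interferon, NF-kB, ATF4, unfolded protein, p53, cell cycle, histone, hypoxia, cholesterol, ribosomal protein and oxidative phosphorylation genes, targets of let-7, miR-21 and miR-16, a breast-to-lung metastasis signature, epithelial and mesenchymal genes, markers of leukocytes, of fibroblasts with endothelium and of luminal breast cells, and 2 transcripts known from the study. For a list of at least 5 measured genes, the median was placed among 10000 random lists of the same size drawn from all genes of the table, as a description. The table holds no expression levels, so the random lists were not matched on expression, and p-values were not computed across genes. On simulated lists of 40 genes, 6 of 100 unshifted lists fell outside the central 95% of random lists, and all 100 lists shifted by 0.1 did. The simulated lists were themselves drawn at random from all genes, so they do not show how lists of related genes behave.

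The rule named TARBP2, APP and ZNF395, the 10 genes with the largest increase and the 10 with the largest decrease among those past the test, filled up by unadjusted p, and up to 4 members of each list by unadjusted p. Because genes had no p-value, size in the authors' deposited table was used instead, and 2 probes each way were named by unadjusted p among probes whose groups did not overlap. Alternatives were no background correction, normexp without negative controls (offset 50), scaling to a common median, the authors' normalized values, other filters on dim probes, eBayes without trend or with the robust option, leaving out each array, and the replicate number as a block. Added after seeing the data were the choice of record per gene, the mean of a list, random lists from the genes of the fixed lists, and the brightest probes alone. Values were also computed with Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The number of arrays limits the precision.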

Results

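The study profiled MDA-LM2 breast cancer cells after knockdown of TARBP2, a double-stranded RNA-binding protein known as a partner of Dicer, to find the transcripts that depend on it. Each of 2 independent siRNAs against TARBP2 gave 1 array, and 2 arrays came from cells with a control siRNA, all taken 48 hours after transfection. Every array measured 47321 probes. On the array of siRNA 1, 21639 probes were detected (45.7%), on that of siRNA 2 20958 (44.3%), on control 1 20393 (43.1%) and on control 2 19411 (41.0%). The raw 75th percentile of the signal was 327.1 on the array of siRNA 1, against 252 for siRNA 2, 241.4 for control 1 and 228.8 for control 2.

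The target gene stood lower in the knockdown. TARBP2 had a mean log fold change of -0.78 over control in the authors' deposited table, read as log2, with -0.98 and -0.58 for its 2 transcript records. The log base of the authors' deposited table is unstated and not settled by its values, which could not be tied to a contrast of the arrays, so sizes depend on reading it as log2. Of the 19468 named genes of the authors' deposited table, 121 had a lower value. ZNF395 and APP, transcripts known from the study, were both above 0 in the authors' deposited table. ZNF395, a zinc finger protein gene, stood at 0.61, with 351 genes above it in the authors' deposited table. APP, the amyloid precursor protein gene, stood at 0.36 in the authors' deposited table, with 0.18 and 0.55 for its 2 records, of which the lower is outside the authors' class 1. These 2 genes were reported by the study from its own data, so their direction here is not independent evidence. The authors' deposited table gives no replicate error, and these values could not be traced to single arrays.

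Across all genes the authors' deposited table was close to symmetric. Of its 19468 genes, 2542 (13.1%) lay above 0.2, the value that bounds the authors' class 1, and 2363 (12.1%) lay below -0.2, the mirrored value. In all, 33 genes lay above 1 and 35 below -1 in the authors' deposited table. The highest gene of the authors' deposited table was G0S2, an inhibitor of triglyceride lipolysis, at 1.92. It was followed in the authors' deposited table by SERPINH1, a collagen chaperone of the endoplasmic reticulum, at 1.39 and the carboxypeptidase gene CPA4 at 1.37. BACC1 (1.35), DAP (1.26), SEL1L3 (1.26), the lysosomal carboxypeptidase gene CTSA (1.23), SERINC2 (1.20), LGALS3BP (1.20) and the pseudogene HLA-H (1.14) completed the 10 highest of the authors' deposited table. HLA-H is nearly identical to other HLA class I genes, so its probe may not separate them. The lowest gene in the authors' deposited table was KIAA1191 at -1.57, followed by STT3A, a catalytic subunit of oligosaccharyltransferase, at -1.52 and TMEM14B at -1.50. The chemokine gene CXCL8 stood at -1.39, the cargo receptor gene TMED5 at -1.36 and YAP1, a transcriptional coactivator of the Hippo pathway, at -1.35 in the authors' deposited table. The authors' deposited table listed SMIM7 at -1.33, the inducible chaperone gene HSPA1B at -1.32, the oncogene NRAS at -1.31 and ECT2, a gene of cytokinesis, at -1.30. HSPA1B shares nearly all of its sequence with HSPA1A, named here outside the rule, which the authors' deposited table listed at -0.59.

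Genes of DNA replication stood lower as a group. The median of the 43 genes of the G1/S and DNA replication list was -0.25 in the authors' deposited table, below all of 10000 random lists, whose central 95% ran from -0.04 to 0.04. Of these genes 24 lay below -0.2 and 3 above 0.2 in the authors' deposited table. PRIM1, a primase subunit, stood at -1.04, the helicase subunit gene MCM6 at -0.87, RPA2 at -0.76 and GINS2 at -0.74 in the authors' deposited table. In the array values, siRNA 1 made up 82.2% of the summed variances of the differences of the siRNAs from the mean control over probes. The differences under the siRNAs had a correlation of -0.005 with different controls. Whether this list or the others described here stood apart under each siRNA was not measured. By their means, leukocyte, epithelial and luminal markers stood higher than random lists in the same table (percentiles 99, 99.97 and 98.5). By their medians these lists lay inside the central 95% (percentiles 82.6, 92.5 and 83.8). The 44 G2/M genes had a median of -0.08 in the authors' deposited table, also below every random list, with 15 below -0.2 and 7 above 0.2. Beside ECT2, HMMR stood at -0.77, while AURKB and KIF20A, both mitotic genes, stood at 0.67 and 0.66 in the authors' deposited table. The 2 records of HMMR in the authors' deposited table stood at -1.21 and -0.34. The G2/M median was no longer outside when random lists were drawn from the fixed lists alone (percentile 5.59).

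Genes of small RNA processing showed no shift as a group. The 22 genes of the list had a median of 0.03 in the authors' deposited table (percentile 85.2 among random lists), with 2 above 0.2 and 1 below -0.2. The helicase gene MOV10 stood at 0.48, the RNA-editing enzyme gene ADAR at 0.24, DICER1 at -0.24 and STAU1 at -0.18 in the authors' deposited table. The records of ADAR in the authors' deposited table differed in sign (-0.13, 0.10 and 0.76), and those of DICER1 stood at -0.42 and -0.05. Among partners of TARBP2, named here outside the rule, AGO2 stood at -0.03, PRKRA at -0.07 and EIF2AK2, the kinase PKR, at 0.01 in the authors' deposited table. Of the target lists of 3 microRNA families, only that of miR-16 lay outside random lists under each choice of record, summary and random lists. The 27 listed targets of the miR-16 family had a median of -0.14 in the authors' deposited table, below all random lists, led by HSPA1B and the heat shock genes CHORDC1 (-0.89) and DNAJB4 (-0.66), with ARL2 at 0.81. The 26 targets of miR-21 had a median of 0.08 in the authors' deposited table (percentile 99.6), with SPRY2 at -0.72, PPIF at 0.59, WWP1 at -0.57 and TIMP3 at 0.52. For the 30 let-7 targets the median was -0.02 in the authors' deposited table (percentile 16.3), whereas their mean of -0.14 had a percentile of 0.07, with NRAS, THBS1 (-0.99) and RRM2 (-0.70) the lowest. The miR-21 list was inside the central 95% when means replaced medians (percentile 69.2) or when random lists came from the fixed lists (percentile 96.6).

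RNA modification and decay genes divided. The 16 genes of the m6A machinery had a median of -0.13 in the authors' deposited table (percentile 0.12), with 7 below -0.2 and 1 above 0.2. RBM15, a subunit of the m6A writer complex, stood at -0.62, HNRNPA2B1 at -0.38 and YTHDF2, a reader, at -0.37, against 0.40 for the demethylase gene FTO in the authors' deposited table. The 34 genes of mRNA decay and nuclear surveillance had a median of -0.02 in the authors' deposited table (percentile 19.6), with 10 below -0.2 and 8 above 0.2. EXOSC10 stood at -0.78, DCP2 at -0.66 and EXOSC6 at -0.64, but EXOSC4 at 0.64 in the authors' deposited table. The 76 cytosolic ribosomal protein genes had a median of -0.06 in the authors' deposited table, below every random list, with 24 below -0.2 and 11 above 0.2, and with RPL13A (0.68), RPS9 (0.63), RPL4 (0.62) and RPL14 (0.60) the farthest from 0. Ribosomal protein genes have many processed pseudogenes, so their probes may be shared. Drawn against random lists from the fixed lists, m6A genes (percentile 5.07) and ribosomal protein genes (percentile 3.52) were inside the central 95%.

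Stress and inflammatory genes went both ways. The 32 genes of the integrated stress response and ATF4 had a median of 0.10 in the authors' deposited table, above every random list, with 8 above 0.2 and 6 below -0.2. SARS1, a tRNA synthetase gene, stood at 1.04, the serine synthesis gene PHGDH at 1.03 and DDIT4 at 0.75, against -0.86 for MTHFD2 in the authors' deposited table. The 23 unfolded protein response genes had a median of -0.06 in the authors' deposited table (percentile 1.15), with ERO1A at -0.89, EDEM1 at 0.57, CALR at 0.48 and PDIA4 at 0.46. The 27 cholesterol synthesis genes had a median of 0.09 in the authors' deposited table (percentile 99.85), with 9 above 0.2 and 8 below -0.2, DHCR7 at 0.81, TM7SF2 at 0.63, MSMO1 at -0.54 and SC5D at -0.49. The 2 records of MSMO1 in the authors' deposited table stood apart, at -0.04 and -1.03. Among the 28 NF-kB targets, whose median was -0.04 in the authors' deposited table (percentile 3.95), CXCL8 was followed by CSF2 (-1.08) and CXCL1 (-0.91), while IL1B stood at 0.97. By its mean of -0.14 the NF-kB list lay outside the central 95% in the authors' deposited table (percentile 0.15). The 42 interferon response genes had a median of 0.02 in the authors' deposited table (percentile 86.4), with 11 above 0.2 and 5 below -0.2. IFITM3, which shares sequence with IFITM2 (0.67), stood at 1.06, IRF1 at -0.999 and IFIT2 at -0.56 in the authors' deposited table. With means in place of medians, the stress list (percentile 96.0), the unfolded protein list (24.0) and the cholesterol list (81.0) were inside the central 95%, and the unfolded protein list was also inside against random lists from the fixed lists (percentile 18.7).

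Of the 25 lists with a median, 9 lay outside the central 95% of random lists, 6 below and 3 above, where chance gives 1.25 for independent lists. With random lists drawn from the genes of the fixed lists, 4 lay outside. Markers of other cell types were among the 16 lists inside. The 20 leukocyte markers had a median of 0.03 in the authors' deposited table (percentile 82.6), but LAPTM5 (0.75), CD74 (0.62), CD14 (0.59) and HLA-DRA (0.36) lay above 0.2 and none below -0.2. The 13 epithelial genes had a median of 0.06 in the authors' deposited table (percentile 92.5), with CLDN7, a tight junction gene, at 1.08 and the keratin genes KRT8 and KRT19 at 1.05 and 0.85. The 18 mesenchymal genes had a median of -0.01 in the authors' deposited table (percentile 29.6), with 2 below -0.2 and 3 above 0.2. Among them CCN2 stood at -0.77 and AXL at -0.52, but COL5A1 at 0.44 and COL1A1 at 0.28. The 17 luminal breast markers (median 0.03) and the 16 fibroblast and endothelial markers (median -0.01) were also inside in the authors' deposited table, the luminal list with KRT8, KRT19, FOXA1 at -0.41 and SPDEF at 0.33, the other with ACTA2 at 0.42 and a mean above 0 (0.03). KRT8 and KRT19 belong to both the epithelial and the luminal list. By means in place of medians the leukocyte (percentile 99), epithelial (99.97) and luminal (98.5) lists lay above the central 95% of random lists. The 30 genes of the breast-to-lung metastasis signature had a median of 0.03 in the authors' deposited table (percentile 86.7), with COL6A1 at 0.88, HTRA1 at 0.80, KRT81 at 0.71 and CXCL1 at -0.91.

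**Figure D1:**
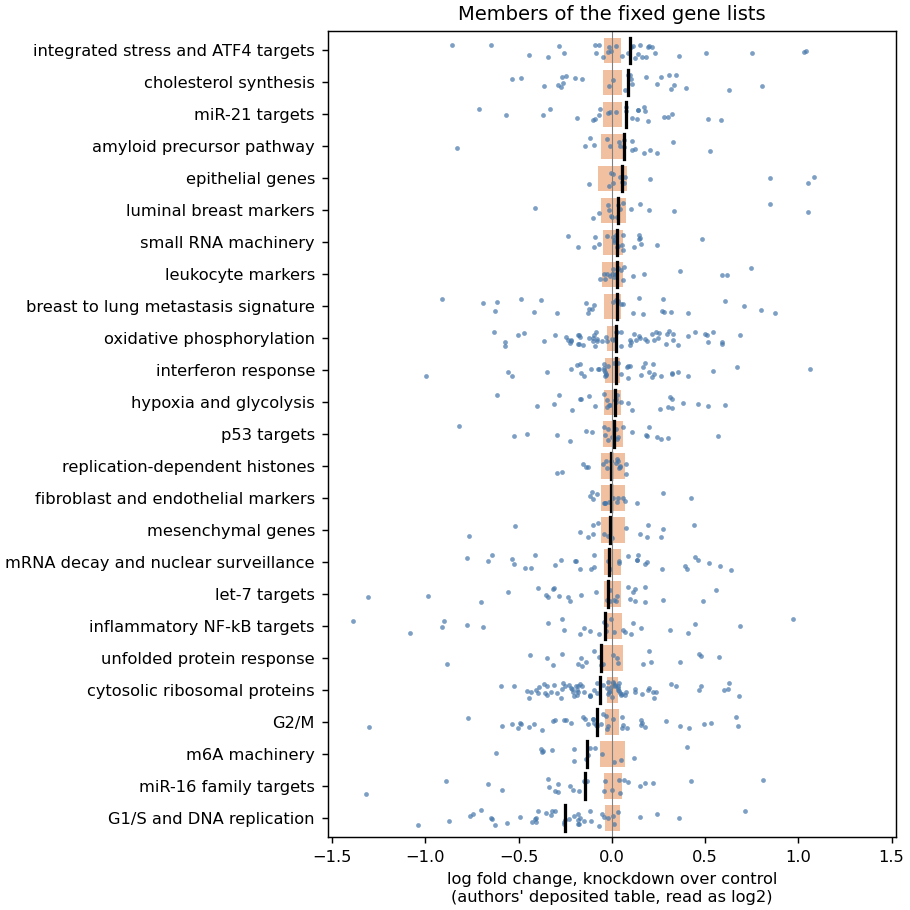
Each point is the log fold change of knockdown over control of a gene in the authors' deposited table, read as log2 (horizontal axis), by fixed gene list (rows, ordered by median). Black bars are list medians and shaded boxes the central 95% of medians of 10000 random lists of the same size. Among these 25 lists of at least 5 measured genes, the G1/S and DNA replication list has the lowest median, at -0.25, and the ATF4 list the highest, at 0.10.

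The array values show how far the replicates support differences between the groups. No probe passed the test of knockdown against control among 21075 tested (limma, smallest adjusted p = 0.805). At an unadjusted p under 0.05 there were 815 probes, 388 higher and 427 lower, where chance gives 1054, and limma without trend gave 818 and with the robust option 755. With 1 array left out the count of probes past the test was 4479 without siRNA 1, 12035 without siRNA 2 and 0 without either control, the lone array being assumed to vary like the other group. The counts of 4479 and 12035 rest on the spread of the control pair, so a noisier lone array gives such counts too. After scaling to a common median in place of quantile normalization the split was 559 higher and 225 lower. Both knockdown arrays lay above both controls for 4082 probes and below both for 4202, together 39.3% of probes, where 4 arrays that vary alike give 33.3%. The arrays did not vary alike: both knockdown arrays lay outside the range of the controls for 73.2% of probes, and random directions then give 36.6%, before the shared controls are allowed for. The share of 39.3% is therefore not read as an excess.

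Among those non-overlapping probes the lowest unadjusted p belonged to ILMN_2184373, with a normalized log2 signal of 10.28 ± 0.29 in the knockdown and 12.16 ± 0.01 in the controls (SD, n = 2 each, limma adjusted p = 0.805). ILMN_2389582 had 5.48 ± 0.15 in the knockdown and 7.40 ± 0.10 in the controls (SD, n = 2 each, limma adjusted p = 0.805). Of the probes with higher values, ILMN_1742330 had 6.33 ± 0.16 in the knockdown and was not well above background on either control array (measured mean 4.83 ± 0.05), a difference of at least 1.92-fold (SD, n = 2 each, limma adjusted p = 0.805). ILMN_1702322 had 5.88 ± 0.11 in the knockdown and was likewise not well above background in the controls (4.56 ± 0.11), at least 1.40-fold apart (SD, n = 2 each, limma adjusted p = 0.805). For these bounds the dim group was set, per array, at the higher of its own signal and the lowest signal among detected probes. They describe the measured values and make no allowance for sampling error or for the choice of extreme probes.

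Of the 6 pairs of arrays, the 2 knockdown arrays were the farthest apart. The log2 differences between the arrays of siRNA 1 and siRNA 2 had an SD of 0.852 over probes, and 22.0% of probes differed by more than 1. The array of siRNA 1 differed from control 1 with an SD of 0.805 and from control 2 with an SD of 0.799. For siRNA 2 these SDs were 0.384 and 0.395, and between the 2 controls the SD was 0.250. Of the summed variances of the 2 siRNAs' differences from the mean control, siRNA 1 made up 82.2%, with their covariance left out. The 2 knockdown arrays were also the farthest apart in the authors' normalized intensities, with an SD of 0.707 between the siRNAs and 0.159 between the controls.

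**Figure D2:**
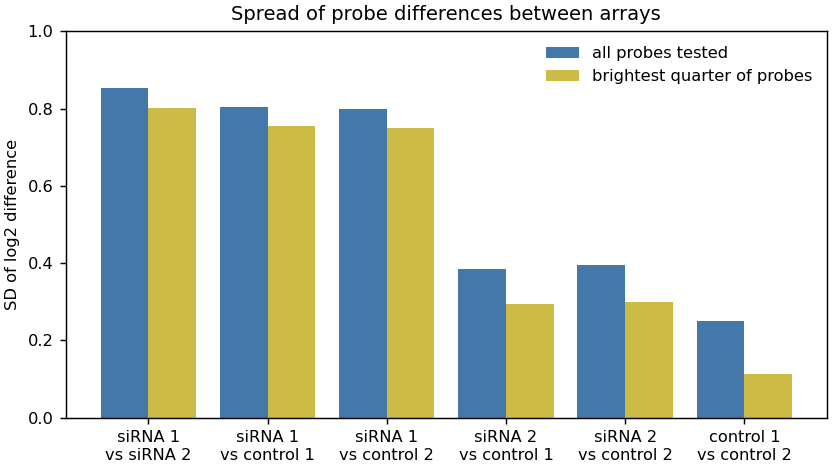
Bars give the SD over probes of the log2 difference (vertical axis) for each of the 6 pairs of arrays, over all 21075 probes tested and over the 5269 brightest. Over all probes tested, the 3 pairs that include siRNA 1 lie between 0.799 and 0.852, against 0.250 for the control pair, and over the brightest between 0.749 and 0.800, against 0.111.

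The differences under the 2 siRNAs were not correlated across probes. With different control arrays, siRNA 1 minus control 1 against siRNA 2 minus control 2, Pearson's r across probes was -0.005 and Spearman's rho was -0.002. With the controls crossed they were 0.024 and 0.024. The sign was shared by 49.9% and 50.8% of probes. With both controls shared r was 0.063 and the covariance was 0.0185. Unchanged arrays with the spread of the control pair gave a covariance of 0.0156 in simulation, from the shared controls alone, which at the observed SDs of the siRNA differences is an r of 0.053. This value is set by the spread of the controls, so it is a baseline and not a separate test. Probes are not independent replicates, and each siRNA had 1 array.

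**Figure D3:**
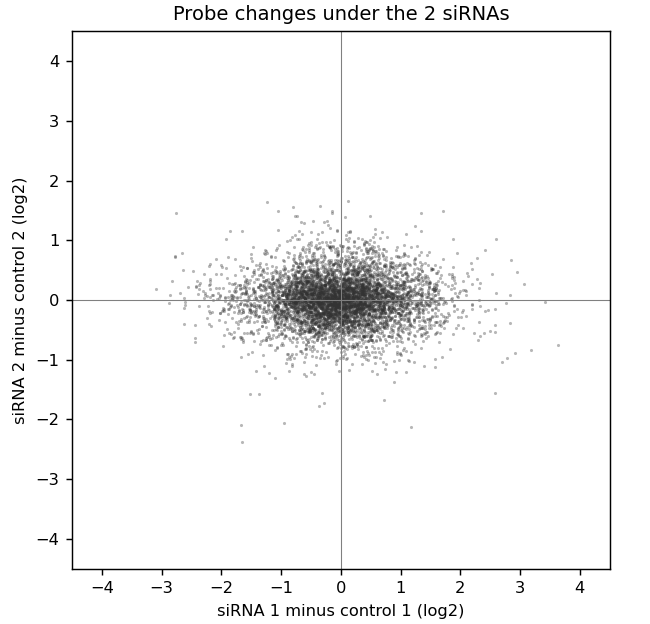
Each point is a probe from a random 6000 of those tested, with the log2 difference of siRNA 1 from control 1 (horizontal axis) and of siRNA 2 from control 2 (vertical axis). The cloud is wider for siRNA 1 and has no slope (r = -0.005 over all 21075 probes).

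Set singly against the 2 controls, with the spread of the control pair and the lone array assumed to vary like it, many probes passed the test under each siRNA, as they would for any array noisier than the control pair. For siRNA 1, 12057 probes passed an adjusted p of 0.05 (limma), 5939 higher and 6118 lower, and for siRNA 2, 4486 passed, 2242 higher and 2244 lower. Of 3275 probes that passed under both, 802 were higher under both, 903 lower under both, and 1570 changed in opposite directions, so that 52.1% shared a direction. Independent lists would share 632 higher, 651 lower and 1283 opposite probes. Part of the excess in shared directions may come from the shared controls, which were too few to be split. Opposite probes were in excess too, which a shared control level would not raise, and the cause was not tested. These counts do not separate effects of an siRNA from noise of its array.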

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

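All tests of explanations under this heading were chosen after the result was seen. The correlation between the siRNAs, which is used in them, had itself been planned. The arrays of the 2 siRNAs lay farther apart than the spread of the control pair allowed for 11559 of 21075 probes (54.8%, limma, adjusted p threshold of 0.05). An array noisier than the control pair gives such calls too, so this count does not show that the effects of the siRNAs differ.

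The array of siRNA 1 stood apart from the other 3, with an SD of 0.792 of its differences from the mean control against 0.369 for siRNA 2. Whether that array responded in a way that depends on intensity could not be decided. A smooth curve on brightness explained 3.10% of the variance of its differences, but the values had been quantile-normalized first. That step already removes much of a smooth shift with brightness, so a low share was likely in advance. Noise of dim probes is argued against, because among the brightest probes the SD of siRNA 1 was still 2.57 times that of siRNA 2. A swapped knockdown and control label would not leave the 2 controls as the closest pair (SD 0.250, next closest 0.384). Whether siRNA 1 gave a stronger form of the response to siRNA 2 could not be decided. The correlation was at most 0.024 with different controls, but a weak response under siRNA 2 amid noise of its array would give a low value too. The level of TARBP2 on each array was not seen, so an unequal knockdown by the 2 siRNAs also stays open. Effects specific to the sequence of siRNA 1 stay open as untested, and a wrongly assigned sample or poor RNA cannot be told apart from them, since 0 probes carried a gene name.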

How the results depend on the processing

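The record of each gene, list means, the listed-gene background and the brightest probes were chosen after seeing the data. No probe passed the adjusted threshold with no background correction, with normexp at offset 50, after scaling to a common median, with the authors' normalized values, without a filter or with the stricter filter on dim probes, without trend, with the robust option, at an adjusted p of 0.10, or with the replicate number as a block (0 probes under each). No shared shift by replicate number was seen across probes (correlation of the differences between siRNA arrays and between controls -0.042). This does not show that the arrays were unpaired. With the replicate block 1019 probes had an unadjusted p under 0.05 (limma). Leaving out 1 array gave between 0 and 12035 probes: 12035 without siRNA 2, 4479 without siRNA 1, and 0 without either control, where the lone array is assumed to vary like the other group and the pair left sets the spread. The count of probes at an unadjusted p under 0.05 was 1740 of 47321 without a filter and 509 of 15393 with the stricter one, and between 157 and 12734 with 1 array left out. On simulated data with the spread of the control pair on all arrays, the test recovered 85.5% of 200 probes changed by 1 on the log2 scale and 99.5% of those changed by 2. With the observed spread of each array it recovered 0 of 200 at either size, so the count of 0 does not bound the number of changed transcripts. The correlation between the siRNAs was 0.024 with controls crossed, -0.010 with the stricter filter, -0.013 with the authors' values and -0.014 among the brightest probes. On crossing the controls, the covariance changes by construction by that of the differences between siRNA arrays and between controls (-0.0089). The crossed value is thus the replicate number check above in another form, and its cause was not tested. Of the gene lists, 9 lay outside random lists, 11 with the largest record of each gene, 10 with means and 4 with random lists from the fixed lists (the cause was not tested), and 2 (G1/S and miR-16 targets) on the low side under each of these choices. The amyloid precursor (percentile 98.5) and luminal (99.1) lists were outside with the largest record. TARBP2 and APP had the same sign in both of their records, ZNF395 had a single record, and alternatives that need the array values of these genes, of the other named genes or of the lists, such as leaving out an array, a block, camera or fry, were not run because probes had no gene names. The median over probes was -0.01 in the main setting and 0.09 after scaling to a common median. The authors' deposited table holds no values per array, so it was not run as such. Signal over background limited the test to 21075 of 47321 probes.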

Other observations

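A scan covered 244 gene families with at least 10 members, formed from the letters that open the symbols and chosen after seeing the data. It found 4 below percentile 0.1 and 3 above percentile 99.9 of random lists drawn from all genes. Independent families of genes drawn at random would give 0.488 together, which need not hold for related genes. The random lists were not matched on expression. A background of fixed-list genes, which cut the fixed lists outside from 9 to 4, was not tried for families. Subunits of respiratory complex I named NDUFA had a median of 0.32 in the authors' deposited table, with 7 of 12 above 0.2 and 1 below -0.2, NDUFA11 at 1.03, NDUFA13 at 0.65 and NDUFA8 at -0.47. Proteasome beta subunits (PSMB) had a median of 0.30 in the authors' deposited table, with 7 of 11 above 0.2 and 1 below -0.2, among the former PSMB10 and PSMB2 at 0.50. The CYB genes, whose shared letters join unrelated cytochrome genes, had a median of 0.22 in the authors' deposited table, with 7 of 13 above 0.2, while the members farthest from 0, CYB5R4 (-0.77) and CYB5R1 (-0.41), lay below -0.2. Exosome subunits (EXOSC) had a median of -0.29 in the authors' deposited table, with 6 of 10 below -0.2 and 3 above 0.2 (EXOSC4 at 0.64, EXOSC7 at 0.46 and EXOSC5 at 0.40). The other families at the low end were centrosomal CEP genes (median -0.11), Mediator MED genes (-0.10) and genes with symbols opening in ARL (-0.08). In the authors' deposited table CEP44 stood at -0.65 and MED10 at -0.57, but MED24 at 0.84. The ARL group was formed by letters alone and need not be a single gene family, and ARL6IP4 in it stood at 0.88. Of the CEP genes 15 lay below -0.2 and 4 above 0.2, of the MED genes 12 and 5, and of the ARL group 9 and 2 in the authors' deposited table.

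Other lists fixed before the data were examined lay inside the central 95% of random lists. The 65 oxidative phosphorylation genes had a median of 0.02 in the authors' deposited table (percentile 91.0), with 20 above 0.2 and 12 below -0.2. The 30 hypoxia and glycolysis genes had a median of 0.02 in the authors' deposited table (percentile 76.9), with BNIP3 at -0.61 and GPI at 0.60. The 24 p53 targets (median 0.01, percentile 62.8, with a mean of -0.02) included PMAIP1 at -0.82 and XPC at 0.57 in the authors' deposited table. The 18 genes of the amyloid precursor pathway had a median of 0.06 in the authors' deposited table (percentile 97.2), with ADAM10 at -0.83 and APLP2 at 0.52. The 17 histone genes had a median of -0.003 in the authors' deposited table (percentile 43.1).

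Genes that lie next to each other in the genome had similar values in the authors' deposited table. Adjacent genes correlated at r = 0.113 over 19443 pairs, above the highest of 1000 shuffles of the genes (0.019), and at 0.110 without pairs whose symbols open with the same letters. The correlation was 0.0846 for genes 5 apart (at most 0.024 in shuffles) and 0.032 for genes 50 apart (at most 0.030). The prediction for a bias shared by neighbours, such as base composition, was written before the result was seen and was met. This is consistent with such a bias of an array or with regional differences in the cells, and neither base composition nor copy number was tested. Which siRNA the pattern came from could not be checked, since the weight of each array in the authors' deposited table is unknown.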
